A study of Mus musculus with 12 samples.

How the data were processed

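The series holds 12 RNA sequencing libraries of mouse embryonic fibroblasts, 3 in each of 4 groups: adeno-GFP (WT) or adeno-CRE (Vps15KO) cells, in basal medium or after 2 h in EBSS. Cells had grown to 90% confluence in high glucose DMEM (4.5 g/L) with 10% serum. Per the labels, poly-A RNA was made into libraries that mark the strand with dUTP and sequenced in read pairs on a DNBSEQ-G400. All libraries carry the same batch label. The submitters' notes name STAR 2.7.10b, featureCounts, DESeq2, limma and the build mm10 without giving the role of each, and the use of the strand in counting is not stated.

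The deposited table gives 32721 genes in 12 columns in log2 units, the authors' variance-stabilizing transformation of counts divided by a size factor per library. Its lowest value, 3.83, is that of a count of 0 and is shared by all columns. From this floor the transformation was inverted. In every library 100% of the values then gave whole reads within a tolerance of 0.001, with size factors of 0.945 to 1.02 and totals of 21278921 to 21698584 reads in genes, so no batch term had been taken out. In 2732 genes all libraries were at 0. A count of 0 allows up to 3 reads of a library for counting error alone. All 32721 symbols matched the mouse RefSeq annotation of the same build, which gave chromosomes and positions. Symbols in the text are those of the table.

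Genes with a mean at least 1 above the floor were tested, 14279 in all. A linear model with a mean per group was fitted to the deposited values with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the variance with the mean (8 residual degrees of freedom, 10.2 prior). The 5 comparisons were the effect of EBSS in each genotype, the effect of Vps15KO in each medium, and the difference of the EBSS effect between genotypes (Vps15KO minus WT, the interaction term). Tests were two-sided, p values were adjusted by Benjamini and Hochberg within a comparison, and a gene was called at adjusted p under 0.05. Log2 changes are differences of the deposited values and understate ratios of genes with few reads. Errors of log2 changes are standard errors of the fit. Normalized counts are worked-back reads divided by the size factor. By the correlation of residuals, replicate numbers did not pair EBSS with basal libraries of a genotype. Between genotypes they may pair. In EBSS, same-number correlations were 0.124, 0.039 and 0.118, and those of different numbers -0.111 to -0.012. In basal medium they were 0.0905, 0.26 and 0.0825, against -0.212 to 0.106. The replicate was a block, across all 4 groups, only in an alternative, and a pairing within a medium was not tested.

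Of 36 gene lists, 30 had at least 5 genes tested and were tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the 150 tests. Camera was also run with the correlation estimated from the data. Limma's fry test was planned and run beside it, and its results are not given here. The lists cover nutrient and stress programs, autophagy and endosomes, lipid and mitochondrial metabolism, chromatin regulators, the matrix, and markers of fibroblasts and other cell types. Cyp4a10, Cyp4a14, Krt5, Krt14, C1qa, C1qb and Myod1 had no entry under those symbols and were not analysed here. The genes named were Pik3r4, the 10 largest rises and falls in each comparison among called genes whose groups did not overlap (for the difference, called genes), without predicted genes and pseudogenes, of which at least 5 a side are given from the largest down, and up to 4 members with the smallest p of each list. Lists, naming rule, tests and most alternatives were fixed before the data were examined. Genes with near-identical copies, such as ribosomal protein genes, metallothioneins, Prl2c2 and MHC genes, have reads that the counting may have assigned unevenly.

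The alternatives were the replicate block, no filter and a filter at 3 above the floor, quantile normalization, equal medians, no variance trend, library weights, only the groups compared, log2 of the normalized count plus 1, adjusted p under 0.01, a log2 change of at least 1, an estimated correlation and each library left out in turn. Where a library was left out, its group kept the pooled spread. Added later were voom on the worked-back reads with the authors' size factors, both WT libraries that stand apart left out, and removal of each library's trends with transcript length and GC content (a spline with 5 degrees of freedom, over 13527 genes with values), which leaves out the mitochondrially encoded list. A change of sign of a list counted only where the list was called in either setting. The fit was tested on simulated data with the mean spread of these libraries at each level of expression. There genes were drawn independently, no library stood apart, and far fewer genes were changed than were called in the real data. For the EBSS effect in WT the fit recovered 54.0% of genes changed 1.25-fold, 76.0% at 1.5-fold and 91.7% at 2-fold, with 5.79% of calls false. For the difference it recovered 12.0%, 73.5% and 81.6%, with 5.44% false. It called 0 of the unchanged lists in either, but with independent genes this says nothing about lists of correlated genes. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 inverted the transformation and drew the figures.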

Results

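Poly-A RNA was sequenced from mouse embryonic fibroblasts with floxed Vps15 alleles (Vps15f/f). Vps15, the product of Pik3r4, is the regulatory subunit of class 3 PI3K, a lipid kinase that acts in autophagy and endosomal sorting. By the labels, cells had been transduced with adeno-GFP (WT) or with adeno-CRE, which carries the recombinase that excises floxed DNA (Vps15KO), while the library names read pLEX_GFP and pLEX_CRE, and no label says what pLEX stands for. They were sampled 5 days later, after 2 h in EBSS, a medium without amino acids, or in basal growth medium. The 4 groups of 3 libraries held 21278921 to 21698584 reads in genes per library. On principal components of the genes tested, the first component took 47.6% of the variance and the second 39.0%, and the 4 groups formed separate clusters on them. In read counts between replicates, WT basal replicate 2 stood apart (chi-square per gene 22.1 and 21.0 against the other replicates, which differed by 3.24), as did WT EBSS replicate 1 (8.45 and 12.2, against 3.92).

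Pik3r4 reads were lower in the Vps15KO libraries of both media. The gene lies on chromosome 9 from 105642995 to 105687655 (mm10). It had 875 ± 10.3 normalized counts in WT basal and 658 ± 36.7 in Vps15KO basal libraries (mean ± SD, n = 3), or 75.1% of WT. In EBSS it had 895 ± 62.7 in WT and 632 ± 35.9 in Vps15KO, or 70.7% of WT. The log2 differences were -0.40 ± 0.07 (SE, adjusted p = 8.41e-05) and -0.48 ± 0.07 (adjusted p = 1.03e-05), and in each medium all 3 Vps15KO libraries lay below all 3 WT libraries. The labels do not name the excised exons, and the values count reads over the whole gene, so they measure neither the share of cells that lost the allele nor the protein. In the main fit EBSS itself left Pik3r4 without a call, with changes of 0.03 in WT and -0.05 in Vps15KO. With length and GC trends removed, a fall in Vps15KO was called.

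**Figure D1:**
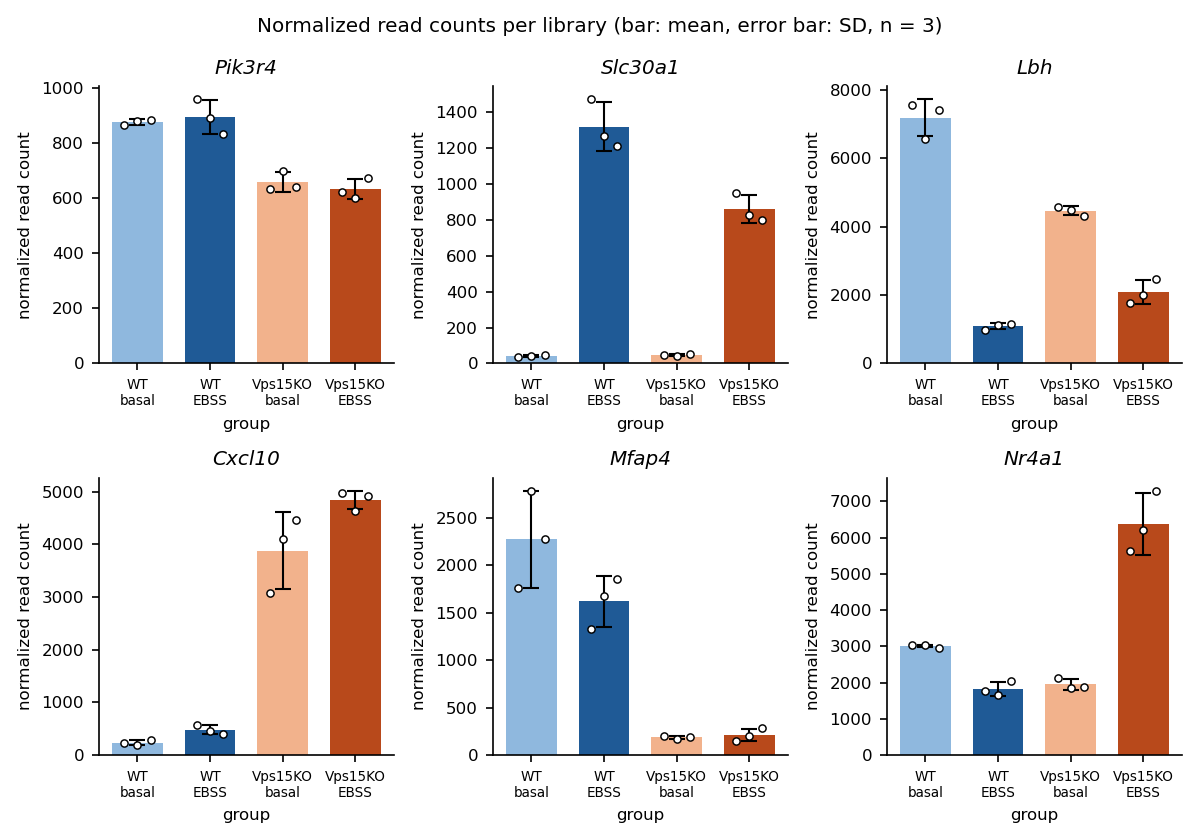
Normalized read count (vertical axis, from 0) of 6 genes in the 4 groups (horizontal axis); bars are means, error bars SD and points the 3 libraries of a group. Slc30a1 went from 40.1 to 1317 in WT after EBSS, Cxcl10 from 235 in WT basal to 3879 in Vps15KO basal, and Nr4a1 fell to 1822 in WT but rose to 6378 in Vps15KO after EBSS.

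In WT cells, EBSS raised Slc30a1, which encodes a zinc exporter, from 40.1 ± 4.96 to 1317 ± 136 normalized counts (SD, n = 3), a log2 change of 4.36 ± 0.10 (SE). Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 3.60 ± 0.13, the receptor subunit Il6ra by 3.14 ± 0.09, the ubiquitin ligase gene Fbxo32 by 3.10 ± 0.07 and the transcription factor Irf4 by 3.09 ± 0.11. Hmox1, which encodes heme oxygenase, rose from 1650 ± 22.4 to 11680 ± 437 counts, and the Wnt ligand gene Wnt9a from 85.7 ± 13.2 to 870 ± 90.0. The largest falls by the selection rule were in Lbh (from 7185 ± 545 to 1091 ± 94.0 counts, log2 change -2.69 ± 0.09), the chemokine gene Ccl7 (-2.61 ± 0.14), Rgs3, a regulator of G protein signalling (-2.48 ± 0.10), Ankrd34a (-2.31 ± 0.12) and LOC115489723 (-2.31 ± 0.12). The comparison asks what the change from basal medium to EBSS does in control cells. Basal medium was high glucose DMEM with serum and EBSS is a salt solution, so the change takes away serum and much of the glucose along with amino acids, and these groups do not separate them. Of 14279 genes tested, 4486 rose and 4468 fell in WT, 558 and 239 of them by a log2 change of at least 1. The 2 groups did not overlap for 9310 genes (65.2%, against 10% by chance).

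FOXO targets, genes driven by the FOXO factors when growth signalling is low, rose in WT as a list. Of 21 tested, 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.55. Fbxo32, Gadd45a (2.00 ± 0.08) and Foxo1 (1.31 ± 0.06) led it. FOXO targets had adjusted p = 8.09e-07, and adjusted p = 0.175 with an estimated correlation. Ribosome biogenesis genes rose at 19 of 28 and fell at 2 (the same counts adjusted over the list alone), among them Tsr1 (1.75 ± 0.08) and Ddx21 (1.01 ± 0.07). Ribosome biogenesis genes had adjusted p = 0.00025, and adjusted p = 0.251 with an estimated correlation. Of 48 ribosomal protein genes, 46 fell and 0 rose (also 46 adjusted over the list alone), by a median of -0.34, Rpl13a by -0.49 ± 0.09 and Rps20 by -0.42 ± 0.08. Ribosomal protein genes had adjusted p = 1.67e-06, and adjusted p = 0.558 with an estimated correlation. Circadian clock genes rose at 12 of 19 and fell at 3 (the same adjusted over the list alone), with Hlf at 2.53 ± 0.11 and Nr1d2 at 1.79 ± 0.09. The clock list had adjusted p = 0.0021, and adjusted p = 0.271 with an estimated correlation. In the list of lysosome and TFEB targets, 18 of 36 rose and 6 fell (the same adjusted over the list alone). The 4 with the smallest p, Fnip2 (from 1386 ± 58.0 to 9156 ± 550 normalized counts), Fnip1 (2.08 ± 0.10), Flcn (1.31 ± 0.06) and Rragc (1.17 ± 0.06), belong to the folliculin and Rag GTPase branch of amino acid sensing rather than to the lysosomal enzymes. The lysosome list had adjusted p = 0.0111, and adjusted p = 0.231 with an estimated correlation. Endosome and retromer genes rose at 17 of 29 and fell at 2 (the same adjusted over the list alone), Vps26a by 1.11 ± 0.06. Endosome and retromer genes had adjusted p = 0.00402, and adjusted p = 0.263 with an estimated correlation.

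The ATF4 amino acid response, the program induced when uncharged tRNA builds up, had 17 of 33 genes higher and 6 lower after EBSS in WT (the same adjusted over the list alone). Its amino acid transporters Slc7a1 (1.85 ± 0.07), Slc38a2 (1.25 ± 0.07) and Slc7a11 (1.48 ± 0.11) rose. The ATF4 list had adjusted p = 0.0489, and adjusted p = 0.682 with an estimated correlation. Leaving out any of 6 libraries (WT basal replicate 1 or 3, WT EBSS replicate 3, Vps15KO basal replicate 2, Vps15KO EBSS replicate 2 or 3) ended that call, with adjusted p from 0.0519 to 0.173, as did quantile normalization (0.116), the replicate block (0.0518) and voom (0.0533). YAP and SRF targets fell at 10 of 18 and rose at 3 (the same adjusted over the list alone), Ccn1 by -1.61 ± 0.13 and Actb by -0.63 ± 0.07. YAP and SRF targets had adjusted p = 0.0389, and adjusted p = 0.387 with an estimated correlation. That call ended without WT basal replicate 1 (adjusted p = 0.0529) and with quantile normalization (0.0512). Nuclear genes of the respiratory chain fell at 17 of 31 and rose at 3 (20 and 3 adjusted over the list alone; adjusted p = 0.0314; adjusted p = 0.599 with an estimated correlation), and the call ended without WT basal replicate 2 (adjusted p = 0.0669). Neither autophagy machinery (14 rose and 8 fell of 31, the same adjusted over the list alone; adjusted p = 0.156) nor class 3 PI3K complexes (4 and 3 of 9, the same adjusted over the list alone; adjusted p = 0.635) was called as a list, although Sqstm1, an autophagy receptor, rose by 1.53 ± 0.07 and Atg14 by 1.29 ± 0.06. Chromatin genes, which the series title concerns, were not called either. Of 34 ATP-dependent chromatin remodellers 18 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.0788), and of 27 histone acetylation enzymes and readers 15 rose and 8 fell (15 and 9 adjusted over the list alone; adjusted p = 0.119), Sirt1 by 2.05 ± 0.10 and Brd2 by 1.23 ± 0.05. Mitochondrially encoded mRNAs fell at 7 of 13 (the same adjusted over the list alone; adjusted p = 0.0702), and their share of reads was 1.03% in WT EBSS replicate 1 against 1.67% and 1.82% in the other WT EBSS libraries. That list was called without WT EBSS replicate 2 (adjusted p = 0.034) or 3 (0.0135) or without WT basal replicate 2 (0.0477), and the remodellers were called without WT EBSS replicate 3 (0.0438).

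Changes after EBSS in WT went with transcript length (Spearman rho 0.307 across genes) and GC content (rho -0.282) over 13527 genes with values. Such trends were not confined to WT, with rho of 0.343 for length and -0.207 for GC content after EBSS in Vps15KO, 0.113 and -0.228 between genotypes in basal medium, 0.0738 and -0.0881 between genotypes in EBSS, and -0.0637 and 0.211 for the difference of the EBSS effects. With each library's trends with both removed, the ribosomal protein median was -0.16 (adjusted p = 0.00472), and the calls of YAP and SRF targets (adjusted p = 0.136) and of the respiratory chain (adjusted p = 0.275) ended.

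In Vps15KO cells, EBSS raised Slc30a1 from 46.0 ± 5.89 to 858 ± 77.9 normalized counts (log2 change 3.63 ± 0.10), Irf4 by 3.05 ± 0.11, Id2, an inhibitor of helix-loop-helix factors, by 2.95 ± 0.12, and Slc23a3 by 2.91 ± 0.13. Angptl4 rose by 3.14 ± 0.13 from 1.30 ± 1.13 counts, a level at which this scale understates ratios. The largest falls by the rule were in Txnip, a glucose-responsive regulator of glucose uptake (-2.16 ± 0.08, from 11740 ± 322 to 2619 ± 276 counts), Ccl7 (-2.11 ± 0.14), Trib2 (-2.10 ± 0.08) and the long noncoding RNAs Mir100hg (-1.97 ± 0.07) and Neat1 (-1.95 ± 0.08). The comparison is the same medium change in cells given Cre. Of the genes tested 3698 rose and 3721 fell, 411 and 88 of them by a log2 change of at least 1, and the 2 groups did not overlap for 8991 genes (63.0%, against 10% by chance).

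Immediate early genes, which encode fast transcriptional regulators such as the Egr and Nr4a factors, rose after EBSS in Vps15KO. Of 31, 23 rose and 6 fell (the same adjusted over the list alone), with a median of 0.79, Nr4a3 by 2.77 ± 0.11, Klf10 by 2.44 ± 0.08 and Egr3 by 2.08 ± 0.09. Immediate early genes had adjusted p = 8.91e-07, and adjusted p = 0.175 with an estimated correlation. Clock genes rose at 15 of 19 and fell at 1 (the same adjusted over the list alone), Ciart by 2.40 ± 0.08 and Nr1d1 by 2.22 ± 0.10. Clock genes had adjusted p = 1.79e-07, and adjusted p = 0.172 with an estimated correlation. Ribosomal protein genes again fell at 46 of 48 (the same adjusted over the list alone), by a median of -0.31 (adjusted p = 8.76e-08; adjusted p = 0.528 with an estimated correlation), and by -0.17 (adjusted p = 0.000593) with length and GC trends removed. The ATF4 amino acid response rose at 19 of 33 and fell at 4 (the same adjusted over the list alone), Sesn2 by 1.78 ± 0.08. The ATF4 list had adjusted p = 0.000265, and adjusted p = 0.442 with an estimated correlation. FOXO targets rose at 12 of 21 and fell at 2 (the same adjusted over the list alone; adjusted p = 0.0095; adjusted p = 0.414 with an estimated correlation). Nuclear genes of the respiratory chain fell at 22 of 31 and rose at 1 (25 and 2 adjusted over the list alone; adjusted p = 5.23e-05; adjusted p = 0.357 with an estimated correlation). Cholesterol synthesis and uptake genes fell at 16 of 25 and rose at 3 (17 and 3 adjusted over the list alone), Hmgcs1, the cytosolic HMG-CoA synthase, by -1.20 ± 0.09. The cholesterol list had adjusted p = 0.000928, and adjusted p = 0.44 with an estimated correlation.

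Histone acetylation enzymes and readers rose in Vps15KO at 14 of 27 and fell at 6 (14 and 7 adjusted over the list alone), among them Sirt1 (2.30 ± 0.10), Brd2 (1.30 ± 0.05) and Kat5 (0.89 ± 0.07). Acetylation enzymes and readers had adjusted p = 0.0153, and adjusted p = 0.172 with an estimated correlation. ATP-dependent chromatin remodellers rose at 16 of 34 and fell at 6 (the same adjusted over the list alone), Chd7 by 1.58 ± 0.13 and Ino80 by 1.16 ± 0.06. Remodellers had adjusted p = 0.0489, and adjusted p = 0.477 with an estimated correlation. The remodellers' call ended with length and GC trends removed (adjusted p = 0.653), with quantile normalization (0.171), with the replicate block (0.0514) and without any of 6 libraries (WT basal replicate 1, WT EBSS replicate 2, Vps15KO basal replicate 1 or 3, Vps15KO EBSS replicate 1 or 3; adjusted p from 0.0513 to 0.093).

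Across genes, the EBSS changes in both genotypes went together, with Pearson r = 0.799 (jackknife SE 0.0168) and a slope of Vps15KO on WT of 0.671 (SE 0.0613). Genes are not independent replicates, and the slope is lowered by noise in the WT changes. In all, 2953 genes rose in both genotypes (1162 if the calls were independent) and 2815 fell in both (1164), while 73 rose in WT and fell in Vps15KO and 102 did the reverse.

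**Figure D2:**
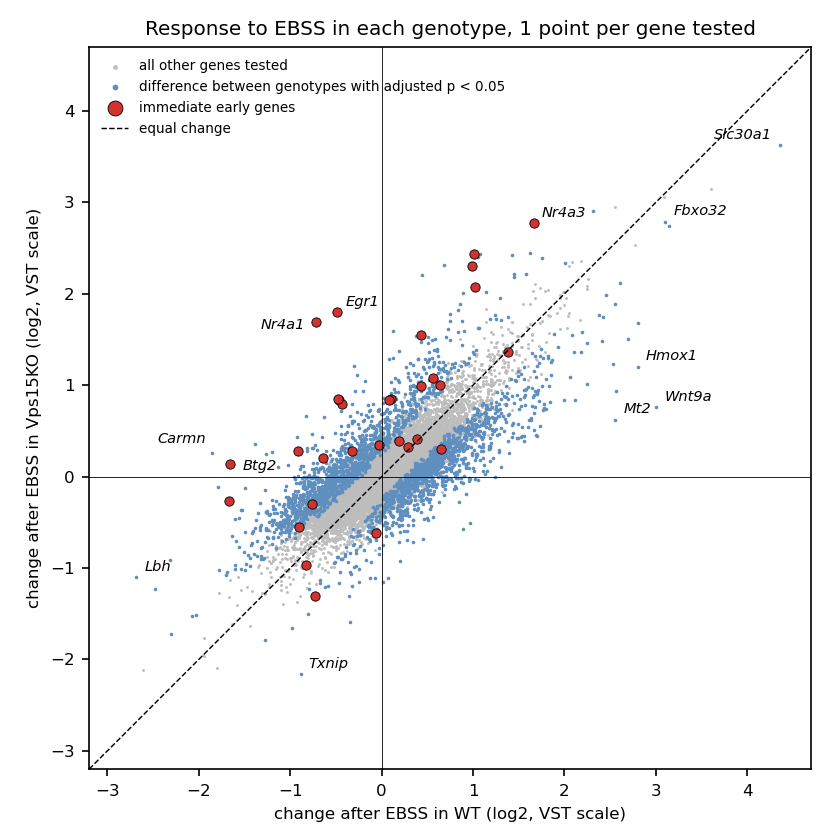
Log2 change after EBSS in WT (horizontal axis) and in Vps15KO (vertical axis), on the variance-stabilized scale, with 1 point for each of 14279 genes; blue points have a difference between genotypes with adjusted p under 0.05, red points are the 31 immediate early genes whether or not they differed, and the dashed line marks equal change. Nr4a1 lies at -0.72 and 1.69, Egr1 at -0.49 and 1.80, Wnt9a at 3.00 and 0.76.

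In basal medium, Vps15KO libraries had more of the interferon-inducible chemokine transcript Cxcl10, 3879 ± 726 normalized counts against 235 ± 46.0 in WT (SD, n = 3), a log2 difference of 3.89 ± 0.13 (SE). The antiviral gene Rsad2 was higher by 3.58 ± 0.14, the chemokine gene Ccl5 by 3.56 ± 0.10 (19306 ± 1264 against 1619 ± 232 counts), the lipase gene Lipg by 3.17 ± 0.17 and Oasl1 by 3.16 ± 0.12. Mfap4, a microfibril protein of the extracellular matrix, was lower at 187 ± 17.5 counts against 2273 ± 514 (-3.40 ± 0.17), as were the noncoding RNA H19 (-2.57 ± 0.08), the matrix genes Thbs2 (-2.47 ± 0.16) and Mfap2 (-2.41 ± 0.13), and the channel gene Trpm5 (-2.39 ± 0.11). The comparison asks what adeno-CRE and a loss of Vps15 change in fed cells, which these groups do not separate. Of the genes tested 4184 were higher and 4169 lower in Vps15KO, 421 and 275 of them by a log2 difference of at least 1, and the 2 groups did not overlap for 8807 genes (61.7%, against 10% by chance).

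Cholesterol synthesis and uptake had the largest median of the 30 lists in basal medium, 1.26. Of 25 genes, 23 were higher and 0 lower (the same adjusted over the list alone), among them Insig1, which holds sterol-sensing proteins in the endoplasmic reticulum (2.43 ± 0.08), Cyp51 (1.65 ± 0.08) and Sqle (1.61 ± 0.08). The cholesterol list had adjusted p = 9.57e-15, and adjusted p = 0.172 with an estimated correlation. The ATF4 amino acid response was higher at 27 of 33 and lower at 2 (the same adjusted over the list alone), Slc7a11, a cystine importer, by 3.06 ± 0.11 and Asns, asparagine synthetase, by 1.56 ± 0.08. The ATF4 list had adjusted p = 4.34e-12, and adjusted p = 0.175 with an estimated correlation. Cytosolic tRNA synthetases were higher at 19 of 21 and lower at 0 (the same adjusted over the list alone), Tars by 1.17 ± 0.06. The tRNA synthetases had adjusted p = 2.84e-09, and adjusted p = 0.175 with an estimated correlation. NRF2 targets, genes of the oxidative stress response, were higher at 20 of 22 and lower at 1 (the same adjusted over the list alone), Abcc4 by 2.05 ± 0.08, Hmox1 by 1.70 ± 0.06 and Gclm by 1.41 ± 0.08. NRF2 targets had adjusted p = 2.32e-09, and adjusted p = 0.172 with an estimated correlation. Cell cycle genes were higher at 30 of 36 and lower at 2 (the same adjusted over the list alone), Cdt1 by 1.20 ± 0.07 and Mcm2 by 1.09 ± 0.06. Cell cycle genes had adjusted p = 3.62e-09, and adjusted p = 0.299 with an estimated correlation. The type I interferon response was higher at 22 of 26 and lower at 1 (the same adjusted over the list alone), led by Cxcl10, Rsad2, Ccl5 and Oasl1. Interferon response genes had adjusted p = 9.45e-08, and adjusted p = 0.35 with an estimated correlation.

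Extracellular matrix genes were lower at 23 of 28 and higher at 3 in Vps15KO basal libraries (the same adjusted over the list alone), Lum by -2.05 ± 0.10, Col1a1 by -1.90 ± 0.09 and Tgfbi by -1.77 ± 0.08. Matrix genes had adjusted p = 2.84e-09, and adjusted p = 0.175 with an estimated correlation. YAP and SRF targets were lower at 13 of 18 and higher at 2 (13 and 3 adjusted over the list alone), Myl9 by -1.80 ± 0.10 and Actb by -1.19 ± 0.07. YAP and SRF targets had adjusted p = 0.000207, and adjusted p = 0.175 with an estimated correlation. Fibroblast markers were lower at 7 of 10 and higher at 2 (the same adjusted over the list alone), S100a4 by -2.10 ± 0.09 and Pdgfrb by -0.88 ± 0.06 (adjusted p = 0.00591, and adjusted p = 0.172 with an estimated correlation). Col1a1 and Dcn stand in both this list and that of matrix genes. Lysosome and TFEB targets were higher at 26 of 36 and lower at 1 (28 and 1 adjusted over the list alone), including the lysosomal hydrolase gene Gla (1.51 ± 0.07), the cholesterol exporter gene Npc1 (0.98 ± 0.06) and Fnip2 (3982 ± 91.0 against 1386 ± 58.0 normalized counts). The lysosome list had adjusted p = 4.41e-07, and adjusted p = 0.169 with an estimated correlation. Endosome and retromer genes were higher at 19 of 29 and lower at 0 (the same adjusted over the list alone), Mtm1, a phosphatase of the lipid that class 3 PI3K makes, by 2.36 ± 0.16 and Vps35 by 0.98 ± 0.07. Endosome and retromer genes had adjusted p = 6.83e-05, and adjusted p = 0.175 with an estimated correlation. In the class 3 PI3K complexes themselves, 6 of 9 genes were higher and 1, Pik3r4, lower (the same adjusted over the list alone), Uvrag by 0.59 ± 0.07 and Atg14 by 0.55 ± 0.06 (adjusted p = 0.17, no call). Sqstm1 was higher by 1.29 ± 0.07. Mitochondrially encoded mRNAs were lower at 9 of 13 (the same adjusted over the list alone), COX3 by -1.42 ± 0.14. The mitochondrially encoded list had adjusted p = 0.0111, and adjusted p = 0.541 with an estimated correlation. Their share of reads overlapped between the groups, with 1.88%, 1.44% and 1.86% in Vps15KO basal against 1.94%, 1.85% and 2.05% in WT basal libraries. Without Vps15KO basal replicate 2, the lowest, the list median went from -0.51 to -0.38 (adjusted p = 0.0351).

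Among markers of blood cells, chosen for mention after their values were seen, Cd68 had 874 ± 15.4 normalized counts in WT basal and 3449 ± 475 in Vps15KO basal libraries, and Cd74 had 46.3 ± 19.5 and 222 ± 22.3. Coro1a had 70.0 ± 18.2 and 37.9 ± 5.60, and the pan-leukocyte gene Ptprc had a mean of at most 0.986 in any group. Cd68 and Cd74 were higher in the same libraries as the interferon and lysosome lists.

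In EBSS, the genes furthest from WT in Vps15KO cells were again Ccl5 (17603 ± 1427 against 1311 ± 148 normalized counts, log2 difference 3.72 ± 0.10), Rsad2 (3.67 ± 0.14), Cxcl10 (3.28 ± 0.13), Oasl1 (3.11 ± 0.12) and Lipg (3.09 ± 0.17), followed by Chac1, a glutathione-degrading enzyme of the ATF4 program (2.92 ± 0.13). Lower in Vps15KO were Mfap4 (-2.82 ± 0.17), Bmf, which encodes a pro-apoptotic protein (-2.60 ± 0.06, 828 ± 33.6 against 5164 ± 151 counts), Pcdh18 (-2.37 ± 0.11), Skida1 (-2.29 ± 0.14), Rasl11b (-2.28 ± 0.13), Aspn (-2.22 ± 0.15) and Angptl4 (-2.22 ± 0.13). The comparison asks the same question in starved cells. Of the genes tested 4201 were higher and 3973 lower, 450 and 298 of them by a log2 difference of at least 1, and the 2 groups did not overlap for 9469 genes (66.3%, against 10% by chance).

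The type I interferon response was higher in Vps15KO EBSS libraries at 25 of 26 genes and lower at 0 (the same adjusted over the list alone). Interferon response genes had adjusted p = 5.86e-13, and adjusted p = 0.217 with an estimated correlation. There Cd68 had 822 ± 51.0 counts in WT and 2849 ± 384 in Vps15KO. The ATF4 amino acid response was higher at 27 of 33 and lower at 1 (the same adjusted over the list alone), Ppp1r15a by 2.39 ± 0.09, Atf3 by 2.13 ± 0.08 and Sesn2 by 1.93 ± 0.08. The ATF4 list had adjusted p = 5.86e-13, and adjusted p = 0.175 with an estimated correlation. Cholesterol synthesis and uptake was higher at 22 of 25 and lower at 0 (the same adjusted over the list alone), Fdft1 by 2.06 ± 0.07 and Msmo1 by 1.95 ± 0.06. The cholesterol list had adjusted p = 4.56e-12, and adjusted p = 0.175 with an estimated correlation. Immediate early genes, which had no call in basal medium (adjusted p = 0.901), were higher at 23 of 31 and lower at 5 (the same adjusted over the list alone), Dusp4 by 2.62 ± 0.11, Fosl1 by 2.61 ± 0.08 and Myc by 1.58 ± 0.07. Immediate early genes had adjusted p = 1.87e-07, and adjusted p = 0.175 with an estimated correlation. Extracellular matrix genes were lower at 21 of 28 and higher at 2 (the same adjusted over the list alone), Col3a1 by -2.02 ± 0.10. Matrix genes had adjusted p = 6.87e-08, and adjusted p = 0.209 with an estimated correlation. Fibroblast markers were lower at 7 of 10 and higher at 1 (the same adjusted over the list alone), with a median of -0.57 against -0.59 in basal medium. The fibroblast list had adjusted p = 0.000274, and adjusted p = 0.169 with an estimated correlation. Fatty acid oxidation and PPAR targets were lower at 13 of 19 and higher at 3 (14 and 4 adjusted over the list alone), Cpt1a, the enzyme that admits long-chain fatty acids to mitochondria, by -1.72 ± 0.07, whereas Acot2 was higher by 2.26 ± 0.09. The PPAR list had adjusted p = 0.00752, and adjusted p = 0.172 with an estimated correlation. Neither chromatin remodellers (10 higher and 16 lower of 34, the same adjusted over the list alone; adjusted p = 0.276) nor histone acetylation enzymes and readers (6 and 11 of 27, the same adjusted over the list alone; adjusted p = 0.328) were called. Across genes, the Vps15KO differences in both media had Pearson r = 0.802 and a slope of EBSS on basal of 0.812, with 2947 genes higher in both (1231 if the calls were independent) and 2828 lower in both (1160).

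The response to EBSS itself differed between Vps15KO and WT libraries. Nr4a1, a nuclear receptor of the immediate early class, fell after EBSS in WT from 3011 ± 39.0 to 1822 ± 198 normalized counts and rose in Vps15KO from 1953 ± 151 to 6378 ± 849 (SD, n = 3), a difference of the log2 changes of 2.41 ± 0.12 (SE). Egr1 fell by 0.49 in WT and rose by 1.80 in Vps15KO (difference 2.29 ± 0.13). The noncoding RNA Carmn (2.11 ± 0.20) and the antiproliferative gene Btg2 (1.79 ± 0.13) fell in WT by -1.85 and -1.66 and had no call in Vps15KO, and Plcxd2 (1.76 ± 0.14) rose in both, by 0.44 and 2.20. On the other side, Wnt9a rose by 3.00 in WT but by 0.76 in Vps15KO (difference -2.24 ± 0.15), the metallothionein gene Mt2 by 2.56 and 0.62 (-1.93 ± 0.12), Add3 by 2.56 and 0.94 (-1.62 ± 0.14) and Hmox1 by 2.80 and 1.20 (-1.60 ± 0.08). Hmox1 had started higher in Vps15KO basal libraries, so its smaller rise does not by itself mean a lower level in EBSS. Evx2 had a difference of -1.47 ± 0.22. The comparison asks whether the response to EBSS differs between the genotypes, with Cre and Vps15 changed together.

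The difference passed the threshold at 2540 genes, 1363 higher and 1177 lower in Vps15KO, 65 and 53 of them by a log2 difference of at least 1. Of the 1363, 378 fell in both genotypes, 452 fell in WT with no call in Vps15KO, 216 rose in both, 212 rose in Vps15KO with no call in WT, 102 fell in WT and rose in Vps15KO, and 3 had a call in neither. Of the 1177, 438 rose in both, 446 rose in WT with no call in Vps15KO, 73 rose in WT and fell in Vps15KO, 172 fell in Vps15KO with no call in WT, 47 fell in both, and 1 had a call in neither. These classes and the difference come from the same libraries.

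Immediate early genes had the largest median difference of the 30 lists, 0.75. Of 31, the difference was higher in Vps15KO at 22 and lower at 3 (23 and 3 adjusted over the list alone), with Ier5 at 1.12 ± 0.08 beside Nr4a1, Egr1 and Btg2. Immediate early genes had adjusted p = 9.57e-15, and adjusted p = 0.169 with an estimated correlation. YAP and SRF targets differed upward at 10 of 18 and downward at 0 (11 and 1 adjusted over the list alone), Ccn1 by 1.14 ± 0.19, Ankrd1 by 0.91 ± 0.15 and Srf by 0.60 ± 0.09. YAP and SRF targets had adjusted p = 1.37e-05, and adjusted p = 0.172 with an estimated correlation. FOXO targets differed downward at 13 of 21 and upward at 2 (14 and 2 adjusted over the list alone), Txnip by -1.27 ± 0.11, Gadd45a by -1.16 ± 0.11 and Bcl2l11, a pro-apoptotic gene, by -1.04 ± 0.11. FOXO targets had adjusted p = 2.92e-07, and adjusted p = 0.175 with an estimated correlation. NRF2 targets differed downward at 8 of 22 and upward at 1 (9 and 1 adjusted over the list alone), Gclm by -1.01 ± 0.11. That list, with Gclm in it, had started higher in Vps15KO basal libraries. NRF2 targets had adjusted p = 8.42e-05, and adjusted p = 0.203 with an estimated correlation. The type I interferon response differed upward at 8 of 26 and downward at 1 (10 and 1 adjusted over the list alone), Mx2 by 1.23 ± 0.19 and Irf9 by 0.69 ± 0.10. Interferon response genes had adjusted p = 5.2e-05, and adjusted p = 0.462 with an estimated correlation. Fatty acid synthesis differed downward at 7 of 17 and upward at 0 (8 and 0 adjusted over the list alone), Lpin1 by -0.94 ± 0.11. The fatty acid synthesis list had adjusted p = 0.00184, and adjusted p = 0.251 with an estimated correlation. Lysosome and TFEB targets differed downward at 12 of 36 and upward at 3 (12 and 4 adjusted over the list alone), Fnip2 by -1.20 ± 0.09. This list, with Fnip2 in it, had also started higher in Vps15KO basal libraries. The lysosome list had adjusted p = 0.00591, and adjusted p = 0.201 with an estimated correlation.

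Autophagy machinery had no call as a list for the difference (0 upward and 4 downward of 31, 0 and 2 adjusted over the list alone, adjusted p = 0.121), with Sqstm1 at -1.08 ± 0.10 and Ulk1, the kinase that starts autophagy, at -0.39 ± 0.08. Sqstm1 had started higher in Vps15KO basal libraries. Chromatin remodellers differed upward at 3 and downward at 4 of 34 (4 and 4 adjusted over the list alone; adjusted p = 0.79), with Chd7 at 0.75 ± 0.18 and Ino80 at 0.45 ± 0.09. Histone acetylation enzymes and readers differed upward at 4 and downward at 1 of 27 (the same adjusted over the list alone; adjusted p = 0.499), Sirt7 by 0.51 ± 0.11 and Sirt6 by 0.50 ± 0.12. Ribosomal protein genes differed at 0 of 48 (also 0 adjusted over the list alone), with a median difference of 0.01, but without WT basal replicate 2 the median was -0.11 with a call (adjusted p = 0.00595). Camera called 72 of the 150 tests of a list in a comparison, and 0 of them with an estimated correlation. The median, mean and camera direction differed in sign in uncalled tests of tRNA synthetases, purine synthesis, NRF2 and p53 targets after EBSS in WT; of tRNA synthetases, PPAR and NRF2 targets, the unfolded protein response and fibroblast markers after EBSS in Vps15KO; of immediate early genes and the unfolded protein response between genotypes in basal medium; and of class 3 PI3K, p53 and neural lists for the difference. The spread behind these tests is that between 3 libraries a group, and nothing in the labels says whether those came from separate cultures.

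**Figure D3:**
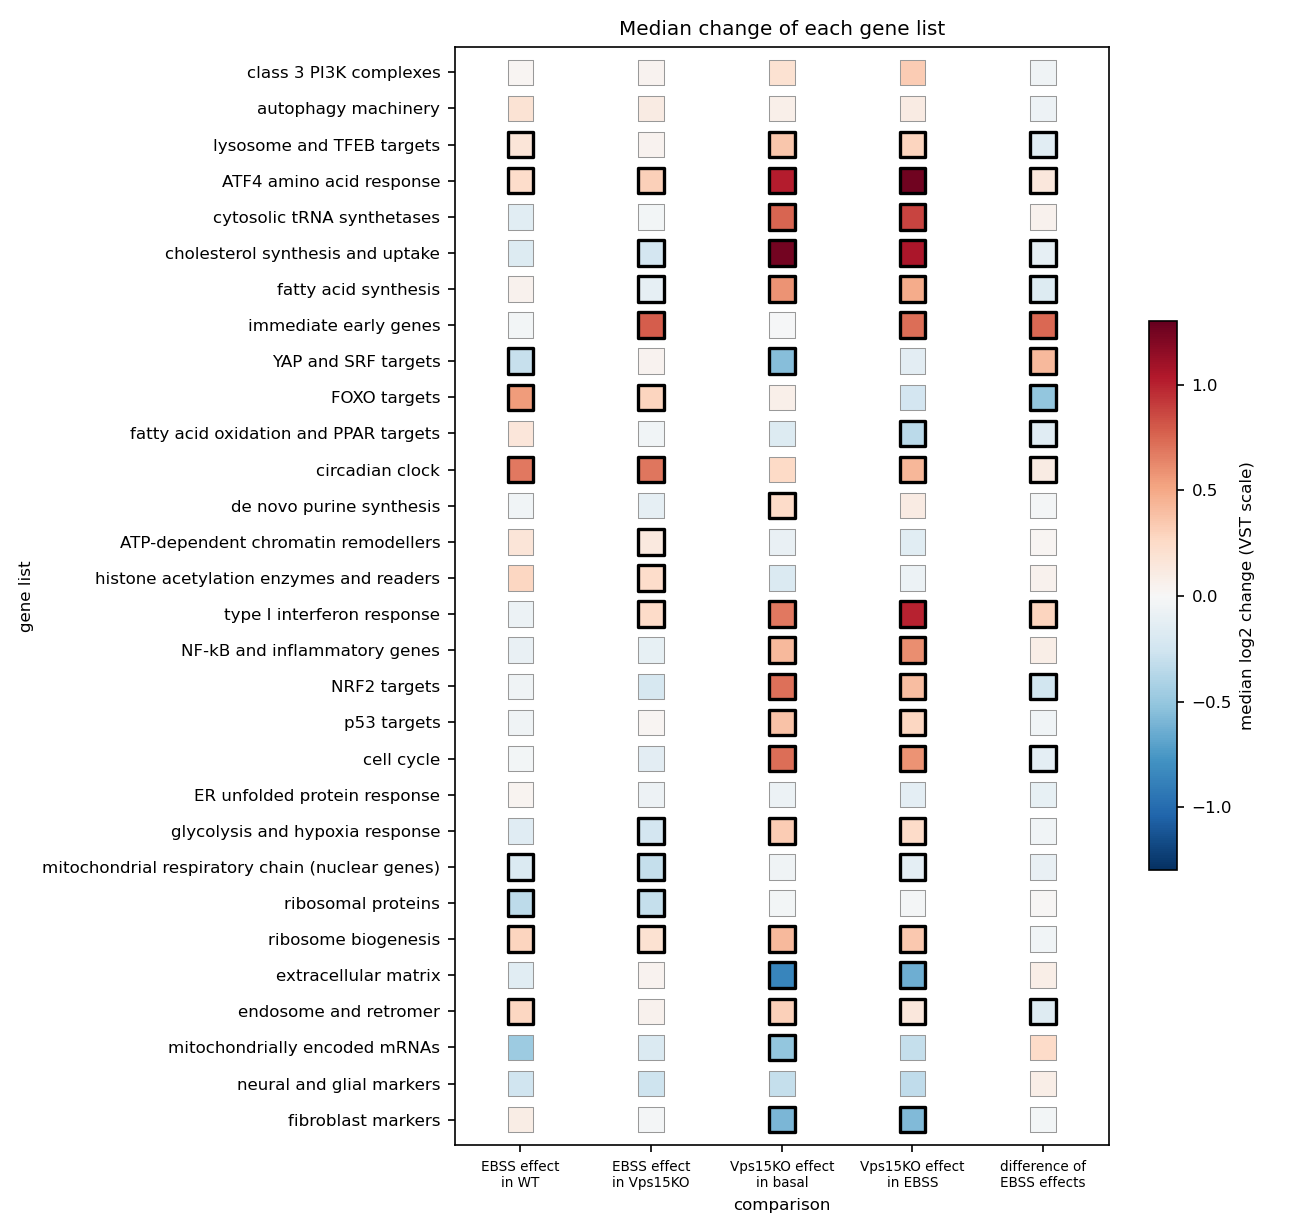
Median log2 change (colour, variance-stabilized scale) of each of the 30 gene lists tested (vertical axis) in the 5 comparisons (horizontal axis); a thick black outline marks an adjusted camera p under 0.05 with the preset correlation. Cholesterol synthesis and uptake has a median of 1.26 in Vps15KO basal libraries, and immediate early genes have 0.79 after EBSS in Vps15KO with no call in WT.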

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

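The permutation of residuals, the removal of length and GC trends, voom and the omission of both WT libraries that stand apart were tests chosen only after the result was seen. The results here share 1 feature: by the interaction term, the EBSS effect differed between WT and Vps15KO cells. The term passed the threshold at 2540 genes. In 7 of 100 draws that permuted the genotype within each medium, the real grouping included, as many genes passed, with 3630 as the highest other. Permuted genotypes bring the genotype difference itself into the term, so these draws cannot decide on chance. In a second scheme, the additive effects of genotype and medium were removed before residuals were permuted. There 1 of 100 draws, the real one, gave as many genes, and the highest other gave 1183. That argues against chance, but the scheme takes all libraries as alike in spread although WT basal replicate 2 stands apart. Chance is thus not excluded, since the planned draws cannot decide and the second scheme has this limit.

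The differences of single genes (Vps15KO minus WT, log2) that were higher were 2.41 for Nr4a1, 2.29 for Egr1, 2.11 for Carmn, 1.79 for Btg2, 1.76 for Plcxd2, 1.75 for Bvht, 1.67 for Trim46, 1.63 for Bhlhe40, 1.59 for Lbh and 1.51 for Pygm. Those that were lower were -2.24 for Wnt9a, -1.93 for Mt2, -1.62 for Add3, -1.60 for Hmox1, -1.47 for Evx2, -1.46 for Nkx3-2, -1.29 for Hlf, -1.28 for Peg10 and -1.27 for both Txnip and Mt1. These are the largest differences among called genes under the naming rule, and each passed at adjusted p under 0.05 in the model of all 12 libraries. Hmox1 among them had started higher in Vps15KO basal libraries.

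Among lists, medians of the difference were 0.75 for immediate early genes, 0.42 for YAP and SRF targets, 0.29 for the type I interferon response, -0.51 for FOXO targets, -0.24 for NRF2 targets, -0.18 for fatty acid synthesis, -0.17 for endosome and retromer genes and -0.15 for lysosome and TFEB targets, whose calls held whichever library was left out at the preset correlation. With an estimated correlation none of these calls stayed (adjusted p from 0.169 for immediate early genes to 0.462 for the interferon response, and 0.263 for endosome and retromer genes). The endosome and retromer median shrank to -0.09 without both WT libraries that stand apart, -0.10 without WT basal replicate 2, and -0.11 without WT EBSS replicate 2 or with length and GC trends removed. The lysosome and TFEB median shrank to -0.09 without WT basal replicate 3 or Vps15KO basal replicate 1, and that of NRF2 targets to -0.14 with quantile normalization. Fatty acid oxidation and PPAR targets had -0.16 (adjusted p = 0.011, and 0.0513 with voom; adjusted p = 0.172 with an estimated correlation). The circadian clock had 0.11 (adjusted p = 0.0253; adjusted p = 0.42 with an estimated correlation), and lost its call without WT basal replicate 3 (median 0.04, adjusted p = 0.083), while without WT basal replicate 2 its median was 0.21. The ATF4 amino acid response had 0.14 (adjusted p = 0.0277; adjusted p = 0.625 with an estimated correlation), and lost its call without both WT libraries that stand apart (adjusted p = 0.0801) and without any of 4 libraries, WT basal replicate 2, WT EBSS replicate 2, Vps15KO basal replicate 3 or Vps15KO EBSS replicate 1 (adjusted p from 0.074 to 0.124). Its median was 0.06 without WT basal replicate 2 and 0.07 without both that stand apart. Cholesterol synthesis and uptake had -0.11 (adjusted p = 0.038; adjusted p = 0.606 with an estimated correlation), and lost its call without both libraries that stand apart (adjusted p = 0.114) and without any of 7, WT basal replicate 1 or 2, WT EBSS replicate 1, Vps15KO basal replicate 2 or 3, or Vps15KO EBSS replicate 1 or 3 (adjusted p from 0.0508 to 0.157), while its median was -0.19 without WT basal replicate 3. Cell cycle genes had -0.13 (adjusted p = 0.0372; adjusted p = 0.695 with an estimated correlation), and lost their call with voom (adjusted p = 0.0533) and without any of 8, WT basal replicate 2 or 3, WT EBSS replicate 2 or 3, Vps15KO basal replicate 2 or 3, or Vps15KO EBSS replicate 1 or 2 (adjusted p from 0.0581 to 0.312). Their median was -0.06 without Vps15KO basal replicate 3 and -0.21 without Vps15KO basal replicate 1.

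The pattern weighed is that immediate early genes rose after EBSS in Vps15KO while 12 rose and 14 fell in WT. With each library's length and GC trends removed, 85.0% of the median difference stayed, which argues against these trends as its cause. Whichever library was left out, the adjusted p of the list was at most 9.68e-13 at the preset correlation, which argues against any single library, although the call is lost with an estimated correlation (adjusted p = 0.169). What stays open is a loss of Vps15 itself, the Cre vector, since all Vps15KO libraries carry it and 0 libraries combine Cre with intact Vps15, and handling, because these genes respond within minutes to a change of medium and the labels give no order of harvest. A dependence of this response on Vps15 is thus a hypothesis, consistent with the values above and untested by an independent sample.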

How the results depend on the processing

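The alternatives with voom, with both WT libraries that stand apart left out and with length and GC trends removed were tests chosen only after the result was seen. Apart from stricter thresholds and libraries left out, the difference passed at 1896 genes with no filter to 3796 with library weights. Every gene shared with the reported calls kept its sign in all settings, except for 10 genes of the EBSS effect in WT and 1 in Vps15KO with length and GC trends removed. A gene called in both fits of nearly the same libraries can hardly change sign, so this adds little support. With libraries left out in turn, genes called ranged from 8142 to 8898 for the EBSS effect in WT, 6273 to 8331 for that in Vps15KO, 7380 to 8332 for Vps15KO in basal medium, 7325 to 9016 for Vps15KO in EBSS and 1863 to 3175 for the difference, list calls from 67 to 74, and the correlation of both EBSS effects from 0.785 to 0.803. Without both WT libraries that stand apart, the 5 counts were 8307, 8525, 8461, 8641 and 3158. With a log2 change of at least 1 they were 797, 499, 696, 748 and 118, since fewer genes can pass, and at adjusted p under 0.01 the difference kept 1227 genes for the same reason. With an estimated correlation 0 of the 72 list calls stayed (adjusted p from 0.169 to 0.695; the cause was not tested). The correlation of the EBSS effects was 0.719 with no filter, where genes near the floor enter, 0.780 with length and GC trends removed and 0.778 with voom (the cause was not tested). Ribosomal proteins turned to a median of 0.11 (adjusted p = 0.0458) between genotypes in basal medium and 0.10 (0.0351) in EBSS with quantile normalization, and their difference of EBSS effects ranged from -0.11 without WT basal replicate 2 to 0.10 without WT basal replicate 1 (the cause was not tested). List calls lost were 3 with the block, 3 with quantile normalization, 3 with voom, 3 with length and GC trends removed and 2 without both libraries that stand apart. Besides the ribosomal protein turns, calls gained were 1 with quantile normalization, 1 with length and GC trends removed and 4 without both libraries that stand apart. Those 4 include the differences for the respiratory chain (median -0.115, camera adjusted p = 0.00227) and the unfolded protein response (-0.17, 0.0309). The others were cholesterol genes after EBSS in WT and mitochondrially encoded mRNAs between genotypes in EBSS. Of the 105 results for named genes outside lists, 2, the Pik3r4 differences between genotypes, fell short of a log2 change of 1, and 1, the EBSS effect on Pik3r4 in Vps15KO, gained a call with length and GC trends removed (-0.18, adjusted p = 0.0228). In the simulated data, 1.25-fold differences between responses were mostly missed. Far fewer genes were changed there than were called here, so that share may not hold for these data.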

Other observations

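The 4 lists of the opening paragraphs, the test of length and GC trends as the whole cause and the removal of these trends were tests chosen only after the result was seen. MHC class I antigen presentation genes, from the heavy chains to the peptide transporter, were higher in Vps15KO at 14 of 16 in basal medium (median 1.18) and at 13 of 16 in EBSS (1.07), and lower at 0 in both. Camera gave adjusted p = 1.19e-08 and 1.6e-07, and adjusted p = 0.0952 and 0.0992 with an estimated correlation. After EBSS they fell at 10 of 16 in Vps15KO (-0.28, camera adjusted p = 0.00978, and 0.372 with an estimated correlation). In WT 7 fell and 3 rose without a call of the list (-0.21, adjusted p = 0.29). The difference had no call either (-0.12, adjusted p = 0.0998, 1 of 16 genes lower), so the fall is not shown to differ between genotypes. Metal response genes, which include the metallothioneins and zinc carriers, rose after EBSS at 6 of 9 in WT (median 0.92, adjusted p = 0.000237; adjusted p = 0.081 with an estimated correlation) and at 7 of 9 in Vps15KO (0.44, adjusted p = 0.00292; adjusted p = 0.0952 with an estimated correlation). The difference was lower in Vps15KO at 7 of 9 (-0.55, adjusted p = 2.13e-06; adjusted p = 0.046 with an estimated correlation). These genes started higher in Vps15KO, at 6 of 9 and lower at 0 in basal medium (0.35, adjusted p = 0.00251; adjusted p = 0.0952 with an estimated correlation), and in EBSS 3 were higher and 4 lower without a call (-0.08, adjusted p = 0.563). The 4 lists were picked because genes of theirs had been seen to move in these libraries, so their p values overstate the evidence.

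HOX genes, the positional transcription factors, fell after EBSS at 11 of 19 in Vps15KO (median -0.37, adjusted p = 0.00143; adjusted p = 0.113 with an estimated correlation) while in WT 4 rose and 6 fell without a call of the list (median -0.05, adjusted p = 0.484). The difference was lower at 7 of 19 (-0.25, adjusted p = 0.00501; adjusted p = 0.154 with an estimated correlation). Imprinted growth genes were lower in Vps15KO EBSS libraries at 5 of 11 and higher at 1 (-0.23, adjusted p = 0.0227; adjusted p = 0.0992 with an estimated correlation). That list had no call in the other 4 comparisons: between genotypes in basal medium (-0.01, adjusted p = 0.136), after EBSS in WT (adjusted p = 0.563) or Vps15KO (0.696), or for the difference (0.519). Among markers of other cell types, chosen for mention after their values were seen, the cartilage regulator Sox9 had 513 ± 28.4 normalized counts in WT basal and 2940 ± 102 in WT EBSS libraries (SD, n = 3), and the adipocyte regulator Cebpa had 122 ± 15.8 and 675 ± 29.1. In Vps15KO they had 856 ± 61.6 and 3482 ± 62.0, and 68.5 ± 4.76 and 235 ± 23.3. Some other markers of these lists had lower means after EBSS in WT, where Fabp4 went from 674 ± 83.9 to 490 ± 19.2 and Runx2 from 800 ± 72.7 to 665 ± 18.4, and Adipoq had a mean of at most 1.35 in any group. The fibroblast marker Thy1 had at most 2.06, and Vim had 150770 ± 3290 in WT basal and 98073 ± 989 in Vps15KO basal libraries.

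The type I interferon response was higher in Vps15KO in both media. If blood cells had brought this RNA, their markers Ptprc, Laptm5, Coro1a, Tyrobp and Fcer1g would be higher too. Summed, they were at 0.572 of WT in basal medium and 0.699 in EBSS. The sum is mostly Coro1a (70.0 counts in WT basal, with Ptprc at 0). It argues against blood cells only as far as Coro1a stands for them. Cd68 (874 to 3449 normalized counts in basal medium, 822 to 2849 in EBSS) and Cd74 (46.3 to 222, and 36.9 to 180) were higher in Vps15KO. Ptprc, Tyrobp, Lyz2, Adgre1 and Itgam, named after their values were seen, had means of at most 1.34 in every group. That argues against blood cells as the source of the rise in Cd68 and Cd74 too. Outside that set, Laptm5 had means of at most 2.96 and Fcer1g of at most 5.81. Csf1r had 2.69 in WT and 6.85 in Vps15KO basal libraries, and 14.5 and 15.4 in EBSS. Whichever library was left out, the adjusted p of the list was at most 3.67e-07 at the preset correlation, which argues against a single library, although the calls are lost with an estimated correlation (adjusted p = 0.35 in basal medium and 0.217 in EBSS). The Cre vector and the loss of Vps15 cannot be told apart for these genes, because 0 libraries carry Cre with intact Vps15.

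Ribosomal protein mRNAs fell after EBSS in both genotypes by small amounts. With length and GC trends removed, 48.1% of the median stayed in the genotype that kept less, between the bounds set for a trend as the cause and for none, so its part in the size is open. As the whole cause it is argued against, since the adjusted p stayed at 0.00472 or less with a fall in both genotypes, but only at the preset correlation, since with an estimated correlation the list has no call even before the trends are removed (adjusted p = 0.558 in WT and 0.528 in Vps15KO). Reads moved to pseudogenes would raise those copies, but the medians of 65 pseudogenes were -0.22 and -0.29. No library decides the pattern (adjusted p at most 2.13e-05 whichever was left out), and a shift of ribosomal protein mRNA with nutrient supply remains a hypothesis consistent with these values.

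A further hypothesis was that losing Vps15 in basal medium moves genes the way starvation moves them in WT. Both changes are measured against the WT basal libraries, which adds covariance. The covariance over genes was 0.0617, 0.0558 above what the shared libraries add, with a standard error of 0.0306 from leaving out libraries. That lies within 2 standard errors, so these samples leave the hypothesis undecided.

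For each of the comparisons of 3 with 3 libraries, 10 splits exist, too few for a share under 0.05. Every split but the real one mixes both groups, so a real effect enters the spread. A count of 0 in the other splits therefore adds no support. For the EBSS effect in WT 1 split, the real one with 8954 genes, gave as many, and the highest other gave 0. For the EBSS effect in Vps15KO 1 split, the real one with 7419, gave as many, and the highest other gave 0. For Vps15KO in basal medium it was 1 split with 8353 and 0 for the highest other, and for Vps15KO in EBSS 1 split with 8174 and 0.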
